A study of Mus musculus with 12 samples.

How the data were processed

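Gene expression was measured in C2C12 cells on single-colour Agilent mouse arrays, with 12 arrays in 4 groups of 3. Per the labels, cells were grown in DMEM with serum, RNA was extracted with TRIzol and labelled with Cy3 by the Agilent one-colour protocol. The titles call the arrays of the pcDNA3.1 group pat1, a name whose meaning is not given, and the group was taken from the transfection field of the labels, which names pcDNA3.1. The labels do not say whether the replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

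Per the file headers, spot intensities on a linear scale were extracted with Agilent Feature Extraction 11.0.1.1, which subtracts the local background and a spatial trend, with no normalisation between arrays. Per the file headers, other columns hold flags of 0 or 1 for spots well above background, not uniform, outlying or saturated. The series table deposited by the authors holds processed intensity values on a linear scale, with column medians of 276 to 277. Its direction is that of the signal, since its ranks correlate with those of the scanner signal at 0.999895 or more on every array, and how its scale was set is not given in the sources used here. It lists 30732 probes, of which 30701 were well above background on at least 3 arrays. Of the 8697 probes it does not list, 7 were.

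Each array held 44397 spots, of which 1377 were controls and were left out, and 0 spots were saturated. Spots marked as outliers were left out and spots of a probe averaged, giving 39429 probes. Probe accessions were looked up without versions in a RefSeq table: 27234 probes matched a symbol, and the other 12195 kept the name in the files. That table is of a later genome build than the one named in the array files, so it served for names only and no coordinates are printed. The log2 of the processed signal was scaled by subtracting each array's 75th percentile. Probes were kept if well above background on every array of at least 1 group (29606 probes). Each gene was represented by its brightest probe, leaving 24516 genes, of which 16768 had a reference symbol. Of the 3037 genes called for the knockdown, 436 had another probe, which went the other way for 120 and past the threshold for 13. Of the 4389 called between the controls these numbers were 627, 206 and 29.

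Replicates were compared before averaging. Replicates 1 and 3 of pcDNA3.1, pcDNA3.1-MEG3 and siRNA shared a slide position, and the deviations of their single spots correlated at 0.975, 0.946 and 0.976, against a median of 0.273 for pairs of arrays of different groups. They were treated as 2 scans of 1 hybridisation and averaged. Replicates 1 and 3 of the negative control were averaged because they differed by less than spot noise (0.740 times) while the other pairs of that group did not. The pairs of replicates 1 and 2 in the other groups also differed by about the spot noise (0.704 times for pcDNA3.1, 0.859 for pcDNA3.1-MEG3 and 1.02 for siRNA) and were kept as 2 samples, which is an uneven treatment. The planned fit used 12 arrays as 12 samples. The change to 8 samples was made after the data, including the counts from 12 arrays, had been seen. Replicate numbers did not pair samples across groups: deviations of same-numbered arrays correlated at -0.0735, -0.0357 and 0.00752 in the comparisons of the plasmids, of siRNA with the negative control, and of the controls.

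The negative control arrays, both plasmid groups and the siRNA arrays lay on separate slides, and the plasmid and siRNA slides were scanned again. Only the plasmid comparison lies within 1 slide. Tests used limma 3.58.1 in R 4.3.3 with the data.table package, version 1.17.8. All 8 samples entered 1 fit with a mean per group (lmFit and eBayes, 4 residual and 1.9 prior degrees of freedom, two-sided), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Groups of 2 samples allow no count over other splits of the samples. The 34 gene lists (995 genes) were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. For some lists the estimate was not above the preset: 0.00962 for autophagy and the lysosome, -0.0122 for immediate early genes and -0.0174 for Wnt targets. A higher adjusted p with an estimated correlation thus does not by itself mean that the genes of a list were correlated. Where all arrays of 1 group were not well above background, only a bound is given: the mean of the brighter group against, per array of the dimmer group, the higher of the lowest signal among probes well above background and the probe's own. The same bound, added after values were seen, is given where only part of the dimmer group's arrays were well above background.

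Before the data were examined, the tests, lists, alternatives and the rule for named genes were fixed. The rule took every Meg3 probe and measured Dlk1-Dio3 gene, the 10 highest and 10 lowest called genes whose groups did not overlap and that had an official-style symbol, and up to 4 members of each list that passed camera or held at least 2 called genes. If no gene passed, it took the 5 highest and 5 lowest with an unadjusted p under 0.05, and for the difference up to 10 called genes. The called transcript of probe A_55_P2416934 has no symbol and was named after its value was seen. A gene that the rule takes is not reported here. The per-gene alternatives were limited, after values were seen, to the locus, the highest and lowest genes, the largest differences, members of lists that passed camera, and the myogenic regulators.

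The normexp alternatives used the median signal of each spot in place of the planned mean signal, a column not used here. Alternatives changed the background correction, scaling, dim probe filter, choice of probe, variance model, array weights, samples in the fit, slide scan block, threshold and test. The fits were tested on simulated data with 24050 genes, of which 50 per fold were changed. At 1.5-fold, 2-fold, 4-fold and 8-fold, 0%, 4%, 50% and 86% were recovered for the overexpression comparison, 0%, 0%, 46% and 78% for the knockdown, 0%, 0%, 42% and 66% for the controls, and 0%, 0%, 14% and 54% for the difference, with 3, 5, 4 and 4 unchanged genes called. A list of 50 genes shifted by 1 log2 was recovered by camera in each of the first 3 comparisons (adjusted p = 6.04e-50, 1.47e-51 and 2.61e-44), with 0 other lists passing. The simulated noise was independent between genes and had the same spread in all groups. Far fewer genes were changed than were called in the real knockdown (3037) and controls (4389), and the share recovered after adjustment depends on how many genes change. Of the 3037 real calls, 1865 were at least 2-fold and the rest were smaller. The simulation therefore cannot show how the tests behave where many genes change, genes are correlated or groups differ in spread, as in the real data.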

Results

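RNA of C2C12 cells, a mouse myoblast line that can form myotubes, was measured on 12 single-colour Agilent arrays 72 h after transfection. By the transfection field of the labels there were 4 groups of 3 arrays: negative control, pcDNA3.1, pcDNA3.1-MEG3 and siRNA. The titles name pcDNA3.1-MEG3 as overexpression and siRNA as knockdown of MEG3. That the plasmid pcDNA3.1 held no insert was assumed here and is not stated in that field. MEG3 is a long non-coding RNA transcribed from the imprinted Dlk1-Dio3 locus. Between 24444 and 29924 of 39429 probes per array were well above background, and the 75th percentile of the signal lay between 1168 and 2266. The small number of arrays limits the precision. In each transfected group other than the negative control, replicates 1 and 3 shared a slide position and differed by an SD of 0.0233 to 0.0234 log2, 0.219 to 0.309 times the noise between spots of 1 array, and were counted as 1 sample. Replicates 1 and 3 of the negative control lay at different positions but differed by less than the spot noise (0.740 times), whereas replicate 2 differed from them by 4.27 and 4.02 times that noise, so that pair was also counted as 1 sample. Replicates 1 and 2 of pcDNA3.1 and of pcDNA3.1-MEG3 also differed by less than the spot noise (0.704 and 0.859 times) but were kept as 2 samples. Under the rule used for the negative control each plasmid group would hold 1 sample, and their comparison would have no replicates. As counted here, each group held n = 2 samples, a change from the planned 12 that was made after the data had been seen. All values below are on the log2 scale after scaling to the 75th percentile, and tests are limma's moderated test with Benjamini-Hochberg adjustment over 24516 genes.

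Meg3 went against the labels of the plasmid groups. Its brightest probe, A_51_P455997, was well above background on 3 of 3 arrays labelled pcDNA3.1 (mean -2.43 ± 0.07, SD, n = 2) and on 0 of 3 arrays labelled pcDNA3.1-MEG3 (mean -7.17). The arrays labelled pcDNA3.1-MEG3 were thus at least 18.8-fold dimmer (log2 difference -4.74, SE 0.46, limma adjusted p = 0.0840, which did not pass, and 8.54e-05 to 0.66 over the alternatives). The second probe, A_55_P2033407, was at least 6.79-fold dimmer there (-3.63, SE 0.67), and the third, A_52_P196568, was not well above background on any array. Within the first scan of the plasmid slide, with 2 arrays per group, the first and second probes differed by -4.83 and -3.66, and within its second scan, with 1 array per group, by -5.11 and -3.47. Neither probe was well above background on the arrays labelled pcDNA3.1-MEG3, so these values give the direction only and not a size. On the negative control arrays the brightest probe was well above background on 1 of 3 arrays (mean -6.69) and on the siRNA arrays on 0 of 3 (mean -7.31), so no fold for the knockdown can be given and its effect on Meg3 could not be checked. Because of this, groups are called by the labels of their arrays, and every direction drawn between the plasmid groups holds for the labels only.

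**Figure D1:**
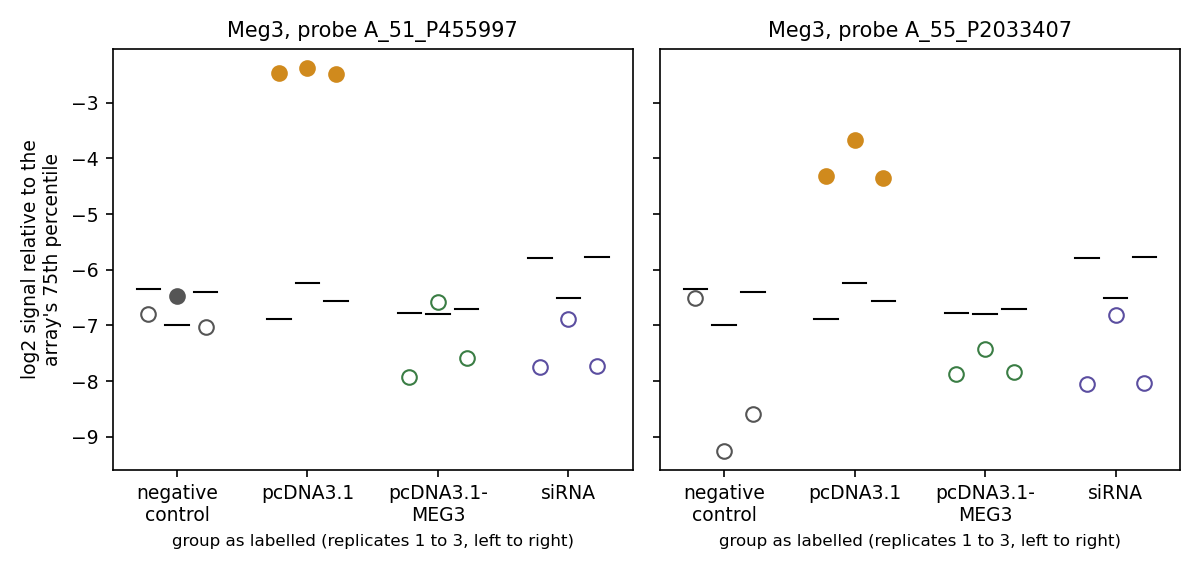
Normalised log2 signal of 2 Meg3 probes on each of the 12 arrays, by labelled group; filled points are well above background and the black dash is the lowest signal among probes well above background on that array. The 3 arrays labelled pcDNA3.1 are filled for both probes, with a mean of -2.43 for the brightest probe against -7.17 on the arrays labelled pcDNA3.1-MEG3.

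The overexpression comparison asked which RNAs differed between the arrays labelled pcDNA3.1-MEG3 and those labelled pcDNA3.1. Prss30, a serine protease gene, fell 21.1-fold on the arrays labelled pcDNA3.1-MEG3 (log2 change -4.40, SE 0.15, n = 2 per group, limma adjusted p = 0.00370). The transcript of probe A_55_P2416934, which has no gene symbol here, fell 10.03-fold (-3.33, SE 0.16, adjusted p = 0.0124). Like Prss30, it was bright on the arrays labelled pcDNA3.1 alone (mean -0.62, against -4.88 to -3.94 in the other groups). These were the 2 genes that passed, and 0 rose. At an unadjusted p under 0.05 there were 2491 genes, where 1225.8 would be expected by chance, and the median over all genes was -0.16. Of the other Dlk1-Dio3 genes measured, Dlk1 (-0.09), Begain (0.09), Mirg (-0.29), Slc25a29 (0.27), Wars (0.17) and Wdr25 (0.67) did not pass.

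Of 34 gene lists, 3 shifted upwards against all other genes in limma's camera on the arrays labelled pcDNA3.1-MEG3, although 0 of their members passed the test over all genes. With fry in place of camera, none of these 3 lists passed (fry adjusted p = 0.0807 to 0.557). The 55 measured type I interferon response genes had a median of 0.05, against -0.16 for all genes (adjusted p = 0.000785, and adjusted p = 0.821 with an estimated correlation), and 4 were higher when adjusted over the list alone. The members with the smallest p were Irf7, a transcription factor of the interferon response (at least 6.49-fold, adjusted p = 0.0840, well above background on 2 of 3 arrays labelled pcDNA3.1), and Bst2, which tethers virions at the cell surface (0.95, SE 0.12). The 33 genes of autophagy and the lysosome had a median of 0.07 (adjusted p = 0.0061, and adjusted p = 0.784 with an estimated correlation). Adjusted over the list alone, 3 of these were higher, among them Wipi1, a protein of early autophagosomes (1.83, SE 0.18, other probe 0.75), and Hexa, a lysosomal hexosaminidase subunit (1.25, SE 0.25). Both were low on the arrays labelled pcDNA3.1 (means -3.11 and 1.21). The arrays labelled pcDNA3.1-MEG3 (-1.29 and 2.45) lay near the negative control (-1.61 and 2.39), and the siRNA arrays were at -3.53 and 1.73. The 50 sarcomere and contractile genes had a mean of 0.14 and a median of -0.01 (adjusted p = 0.0304, and adjusted p = 0.821 with an estimated correlation). The median was 0.05 with quantile normalisation, and the adjusted p became 0.0929 without pcDNA3.1-MEG3 replicate 2 and 0.0532 with 12 arrays as 12 samples. Adjusted over the list alone, 2 were higher. Values were 1.37 for Tnni1 and 0.86 for Tnnc1, both troponin subunits, and 2.17 for Des, the muscle intermediate filament. Myh6, a cardiac myosin heavy chain, was at -0.99 (SE 0.24), and its other probe at 0.43. Des was low on the arrays labelled pcDNA3.1 (-4.23), and those labelled pcDNA3.1-MEG3 (-2.06) lay near the negative control (-2.77, SD 1.15). Tnni1 and Tnnc1 lay above the negative control on the arrays labelled pcDNA3.1-MEG3 (-3.27 against -4.22 and -1.38 against -3.10). Counting 12 arrays as 12 samples gave 2997 genes (1496 higher and 1501 lower). The main fit shares 1 spread over all groups, although the plasmid samples varied less than the negative control samples. The plasmid samples differed by less than the spot noise (0.704 times for pcDNA3.1 and 0.859 for pcDNA3.1-MEG3), so their spread may be technical. Whether the shared spread was too wide here therefore cannot be told, and larger counts from narrower spreads are not better founded. Fitting the arrays of the compared groups alone gave 1960, and leaving out either sample of either group gave 0.

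The knockdown comparison asked which RNAs differed between the siRNA arrays and the negative control. The transfection field of the labels reads only negative control and does not say whether these cells received a control siRNA. Any effect of siRNA transfection itself may thus be part of this comparison. Contractile protein genes were among those that rose most on the siRNA arrays. Actc1, the cardiac alpha-actin, rose 142-fold (log2 change 7.15, SE 0.47, n = 2 per group, limma adjusted p = 0.00126), Myh3, the embryonic myosin heavy chain, rose 132-fold (7.05, SE 0.45) and Myl1, a myosin light chain, rose 96.6-fold (6.59, SE 0.24). The negative control samples lay far apart for Actc1 (SD 1.11) and Myh3 (SD 1.04), so the size of these folds is uncertain. Vgll2, a cofactor of TEAD transcription factors expressed in muscle, rose at least 203-fold, and Pdlim3, a protein of the Z-disc, rose 129-fold. Cbx7, a Polycomb protein, fell at least 14.9-fold and Fkbp11, a peptidyl-prolyl isomerase of the endoplasmic reticulum, fell with a log2 change of -4.14 (SE 0.75). Both were bright in the negative control alone, Cbx7 at a mean of -2.25 against -7.77 to -6.96 in the other groups and Fkbp11 at 1.32 against -4.90 to -2.82, so neither drop was particular to the siRNA arrays.

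Of 24516 genes, 1900 were higher and 1137 lower, and the median over all genes was 0.06. Also among the 10 highest were Tspan7 (at least 299-fold), Alox5, the 5-lipoxygenase (log2 change 7.30), Nefl, the neurofilament light chain (at least 50.6-fold) and Tceal7 (at least 62.0-fold). Tspan7, Nefl and Tceal7 were well above background on 1 of 3 negative control arrays each. Among the lowest were Lyar, a nucleolar protein (at least 10.4-fold lower), Rspo3, a secreted enhancer of Wnt signalling (at least 8.29-fold lower), and Cox17, a copper chaperone of cytochrome oxidase (-3.44). Lyar and Cox17 were also brightest in the negative control, with means of -2.74 and -1.24 against -6.57 to -6.01 and -4.68 to -4.22 in the other groups. Of these 3, only Rspo3 was low on the siRNA arrays alone (-6.43, against -3.10 to -2.85 elsewhere). Also among the 10 lowest, H2-M10.1 (-5.49, against -1.87 to 1.21 elsewhere), Avil (-5.49, against -1.94 to -0.26) and Pdzrn4 (-7.62, against -4.20 to -3.07) were lowest there. They were well above background on 1, 1 and 0 of 3 siRNA arrays. Ubxn4 and Serpinb1c, the remaining genes of the 10, were brightest in the negative control. Of the Dlk1-Dio3 genes measured, none passed here. Begain was at 0.43, and Dlk1, which was well above background on 1 of 3 siRNA arrays, at -0.95 (SE 0.97) and at 0.65 without siRNA replicates 1 and 3.

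Of the 50 sarcomere and contractile genes, 36 rose, 0 fell and 14 did not pass. Adjusted over the list alone, 41 were higher and 1 lower. Their median was 2.56, or 2.36 with genes of an undetected group at their bound (camera adjusted p = 3.3e-26, and adjusted p = 0.0427 with an estimated correlation). Members included Casq2 (5.78, SE 0.21), a calcium-binding protein of the sarcoplasmic reticulum, Mb, myoglobin (4.45, SE 0.14), Ryr1, the calcium release channel (4.05, SE 0.12), and Tnnt3, the fast troponin T (3.99). Of 20 myoblast fusion genes, 7 rose and 0 fell, with 9 higher adjusted over the list alone (median 0.58, camera adjusted p = 0.00999, and adjusted p = 0.479 with an estimated correlation). The fusogens Mymx and Mymk rose 13.9-fold and 7.58-fold, and Cdh15, M-cadherin, rose 2.66-fold. Of 17 myogenic regulators, 6 rose and 3 fell, the same counts as adjusted over the list alone. The list did not pass camera (adjusted p = 0.38), although it passed fry upwards (adjusted p = 0.000905). In this comparison fry passed 19 of 34 lists, so passing it was not particular to a list. Myog, the transcription factor that starts terminal differentiation, rose 11.04-fold (3.46, SE 0.15). Myf5, a transcription factor of proliferating myoblasts, fell 7.30-fold (-2.87, SE 0.33), but it was dimmer still on both plasmid groups, where it was well above background on 1 of 3 arrays labelled pcDNA3.1 and 0 of 3 labelled pcDNA3.1-MEG3. The siRNA arrays lay at least 2.69-fold and 3.67-fold above these. Neural markers were raised in part, with 4 of 12 rising and 2 falling, against 5 and 2 adjusted over the list alone (median 0.52, camera adjusted p = 0.157, which did not pass, and fry adjusted p = 0.000109). The siRNA arrays had the fewest probes well above background (62.0 to 68.6%, against 69.2 to 75.9% on the others) and the most probes with every spot marked as outlying (232 to 431, against 23 to 107).

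Of 46 genes of G1/S and DNA replication, 21 rose and 1 fell, against 27 and 2 adjusted over the list alone (median 0.71, camera adjusted p = 1.54e-07, and adjusted p = 0.362 with an estimated correlation). Tyms, thymidylate synthase, rose by 1.43 (SE 0.14) and Mcm10, a replication initiation factor, by 1.30 (SE 0.14). Against the negative control, the arrays labelled pcDNA3.1 also had 12 of these genes higher and 2 lower (median 0.41, camera adjusted p = 0.0883, which did not pass), and against both plasmid groups the siRNA arrays had 9 higher and 1 lower (median 0.25, camera adjusted p = 0.000966, and adjusted p = 0.197 with an estimated correlation). Of 33 immediate early genes, 12 rose and 1 fell, against 14 and 2 adjusted over the list alone (median 0.38, camera adjusted p = 0.0279, and adjusted p = 0.362 with an estimated correlation). Without siRNA replicate 2 the adjusted p was 0.131. Fos rose by 1.79 (SE 0.15) and Klf2 by 1.58 (SE 0.15). Of 55 type I interferon response genes, 18 rose and 3 fell, against 20 and 3 adjusted over the list alone (median 0.34, camera adjusted p = 0.00177, and adjusted p = 0.542 with an estimated correlation). Oas2, an activator of RNase L, rose at least 5.11-fold and Usp18, which removes ISG15 from proteins, rose by 2.60 (SE 0.20). The 65 cytosolic ribosomal protein genes shifted down (median -0.17, camera adjusted p = 0.00811, adjusted p = 0.787 with an estimated correlation, and fry adjusted p = 0.445). Of these Rpl19 fell by 0.90 (SE 0.17), 0 rose, and 0 passed adjusted over the list alone. The list no longer passed with quantile normalisation (adjusted p = 0.128) or without siRNA replicate 2 (adjusted p = 0.131).

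The negative control slide and the siRNA slide were scanned separately and each held 1 group, so batch and group cannot be told apart. The negative control alone was scanned in a different calendar month from all other arrays. Its replicate 2 had a 75th percentile of the signal of 2266, against 1601 or less on every other array. The main fit shares 1 spread over all groups, although the siRNA and negative control samples varied more than the plasmid samples, so its test was lenient here. The count of 3037 genes became 9839 with 12 arrays as 12 samples, 156 with the arrays of the compared groups alone, 7357 without negative control replicate 2, 7440 without its replicates 1 and 3, 4795 without siRNA replicate 2 and 1948 without siRNA replicates 1 and 3. The split of 62.6% higher calls became 41.1% with median centring, which moved the median of all genes to -0.13.

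**Figure D2:**
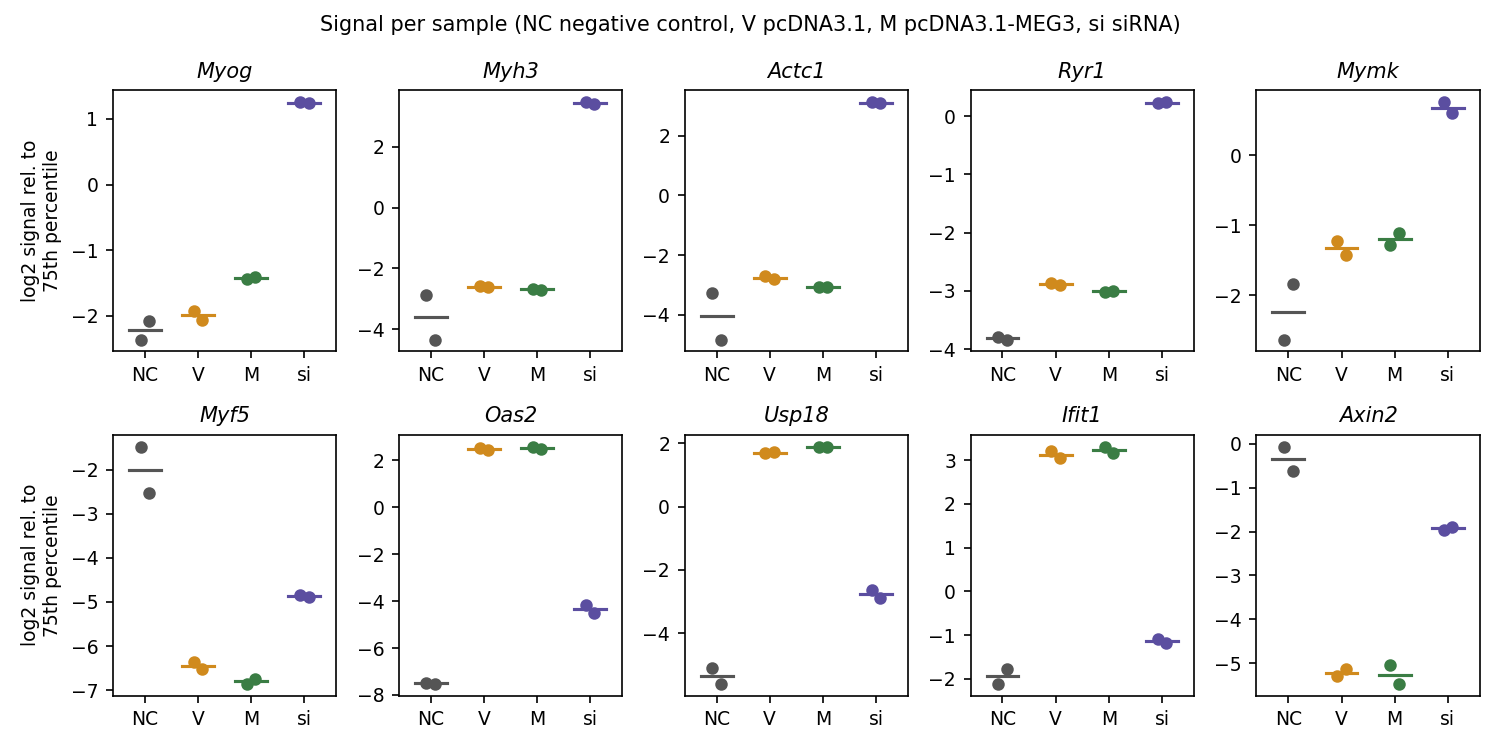
Normalised log2 signal of 10 genes in each of the 8 samples by labelled group; in each group the left point is the mean of replicates 1 and 3, the right point is replicate 2 and the line is the group mean. Myog, Myh3, Actc1, Ryr1 and Mymk lie highest on the siRNA arrays (Myog 3.46 above the negative control), and Oas2, Usp18 and Ifit1 lie higher on both plasmid groups than on the negative control (Usp18 7.07 for pcDNA3.1).

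The comparison of the controls set the arrays labelled pcDNA3.1 against the negative control and shows how far these groups differed. Interferon response genes rose most on the arrays labelled pcDNA3.1. Oas2 rose at least 577-fold, Usp18 134-fold (log2 change 7.07, SE 0.20, n = 2 per group, limma adjusted p = 0.000144) and Rsad2, the antiviral protein viperin, at least 84.0-fold. Ifit1, which binds foreign RNA caps, rose by 5.07 (SE 0.17). Oas1a rose at least 507-fold and was well above background on 1 of 3 negative control arrays. Axin2, a feedback inhibitor of Wnt signalling (-4.88, SE 0.24), and Postn, a matrix protein (-2.65, SE 0.24), fell.

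Of 24516 genes, 2765 were higher and 1624 lower, and the median over all genes was 0.22. Meg3 rose at least 16.0-fold (adjusted p = 0.00523, well above background on 1 of 3 negative control arrays). Of the 55 interferon response genes, 47 rose and 0 fell, against 50 and 1 adjusted over the list alone (median 2.62, unchanged with undetected genes at their bound, camera adjusted p = 1.51e-26, and adjusted p = 0.101 with an estimated correlation). Of 54 extracellular matrix genes, 3 rose and 17 fell, against 3 and 22 adjusted over the list alone (median -0.47, camera adjusted p = 9.32e-08, and adjusted p = 0.0691 with an estimated correlation). Col14a1 (-1.82) and Thbs2 (-1.38) fell, and Mmp13, a collagenase, rose (2.69, SE 0.17). Of 25 Wnt targets, 1 rose and 7 fell, the same counts as adjusted over the list alone (median -0.42, or -0.36 at the bounds, camera adjusted p = 0.00011, and adjusted p = 0.101 with an estimated correlation). Dkk2 (-2.30, SE 0.14), Nkd2 (-2.31, SE 0.22) and Sfrp2 (-1.33), modulators of Wnt signalling, fell. Of 32 TGF-beta response genes, 0 rose and 8 fell, against 1 and 9 adjusted over the list alone (median -0.16, camera adjusted p = 0.00408, and adjusted p = 0.413 with an estimated correlation). Ccn2 (-2.04, SE 0.14), Smad7, an inhibitor of the pathway (-1.86, SE 0.18), and Tagln, transgelin (-3.14, SE 0.22), fell. Markers of fibroblasts and smooth muscle were lower too, with 6 of 14 falling and 0 rising, against 7 and 1 adjusted over the list alone (median -0.69, camera adjusted p = 0.00284, and adjusted p = 0.66 with an estimated correlation). Of the 16 genes of that list, 8 also stood in another list, Postn and Tagln among them.

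Among the lowest genes were Ubxn4 (at least 30.8-fold), Wdr19 (at least 31.9-fold), Cbx7 (at least 18.8-fold) and Spry4, an inhibitor of growth factor signalling (at least 10.5-fold). All 4 were bright in the negative control alone, at -1.53 for Ubxn4 (-8.21 to -5.26 elsewhere), -1.41 for Wdr19 (-6.99 to -4.51), -2.25 for Cbx7 (-7.77 to -6.96) and -3.08 for Spry4 (-8.07 to -5.86), so these drops were not particular to pcDNA3.1. Myf5 fell at least 19.6-fold (well above background on 1 of 3 arrays labelled pcDNA3.1) and was also brightest in the negative control. The groups lay on separate slides scanned in different calendar months, so batch and group cannot be told apart. The count of 4389 genes became 12072 with 12 arrays as 12 samples, 7408 without negative control replicate 2, 9155 without its replicates 1 and 3, 1285 without pcDNA3.1 replicate 2 and 524 without pcDNA3.1 replicates 1 and 3. The split of 63.0% higher calls became 19.8% with median centring (median of all genes -0.23), 47.3% with quantile normalisation and 47.1% with the authors' processed values.

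**Figure D3:**
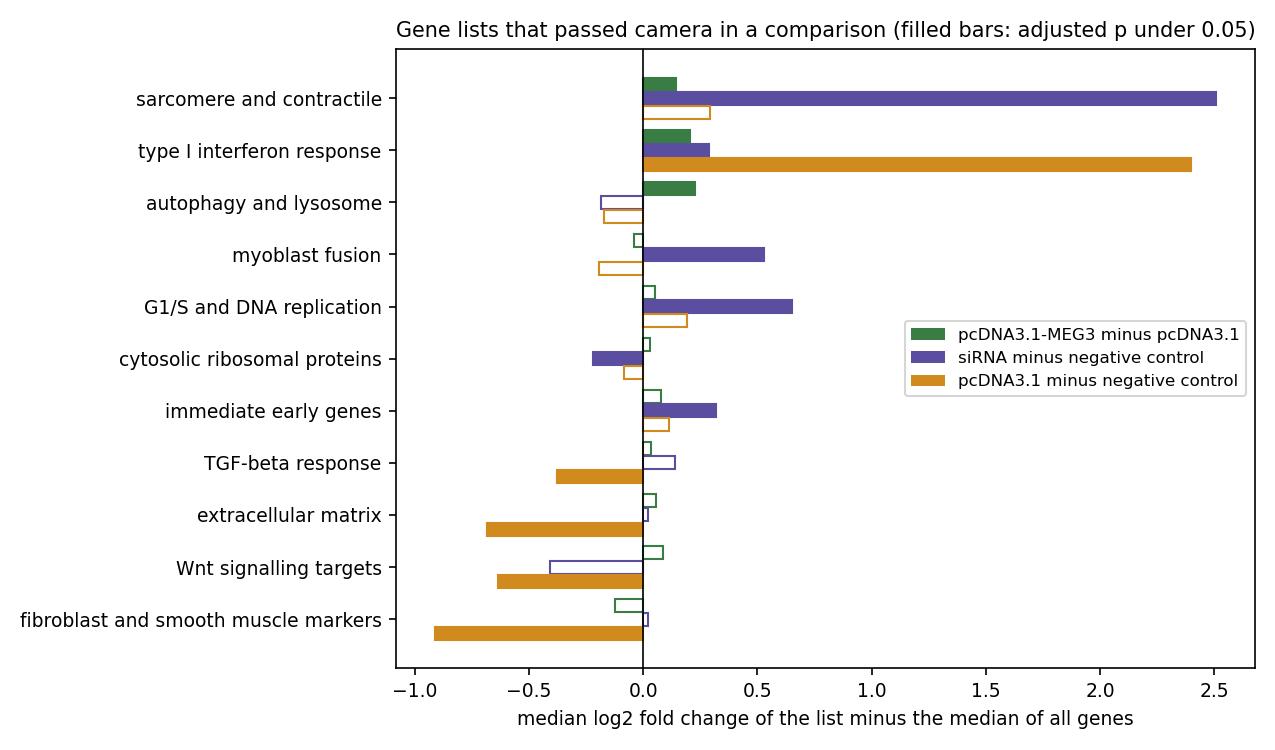
Median log2 difference of gene lists minus the median of all genes (log2), for lists that passed camera in at least 1 comparison. Filled bars have an adjusted p under 0.05. Contractile genes stand highest for siRNA against the negative control (median 2.56 before subtraction) and interferon response genes for pcDNA3.1 against the negative control (2.62).

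The difference between both effects, overexpression minus knockdown, asked which genes responded differently. As labelled, the 10 largest differences were all negative, and contractile genes were among them: Actc1 (-7.46, SE 0.67, n = 2 per group, limma adjusted p = 0.00551), Myh3 (-7.14, SE 0.63) and Myl1 (-6.59, SE 0.35). Alox5 (-7.43) and Pdlim3 (-7.32) were also among them. Tspan7, Vgll2, Bace2 and Nefl stood there too, but were well above background on 1, 0, 0 and 1 of 3 negative control arrays, so their places rest on fitted signals near background and no difference is printed for them. With the sign of the plasmid comparison turned, as an exchange of its labels would do, the 10 largest were also all negative, 8 of them shared, and Actc1 was at -6.84, Myh3 at -6.95 and Myl1 at -6.60. The means on arrays labelled pcDNA3.1 and pcDNA3.1-MEG3 were close for Actc1 (-2.76 and -3.07), Myh3 (-2.60 and -2.69) and Myl1 (-0.97 and -0.96). Their differences thus mostly restate the knockdown change with its sign reversed, and turning the plasmid sign could hardly alter them. In all, 874 differences were positive and 1221 negative as labelled, against 241 and 363 with the sign turned, where 480 genes were called both ways. The 2 genes called for the plasmids, Prss30 and that of probe A_55_P2416934, were also called for the knockdown, in the opposite direction as labelled and in the same direction with the sign turned, where 0.248 shared genes would be expected of independent lists. Across genes, which are not independent replicates, the log2 changes of both comparisons correlated at r = -0.193, or 0.193 with the sign turned. Prss30 was bright on the arrays labelled pcDNA3.1 alone, with a mean of 0.44 against -4.93 in the negative control, -3.96 on the arrays labelled pcDNA3.1-MEG3 and -4.22 on the siRNA arrays. In the same order, the means for probe A_55_P2416934 were -0.62, -4.88, -3.94 and -3.98. The knockdown changes of both genes were thus far smaller than their plasmid changes (-4.40 and -3.33), and their overlap does not show a reciprocal response. The split of 41.7% positive calls became 62.5% with median centring, and the count of 2095 became 8874 with 12 arrays as 12 samples, 5744 without negative control replicate 2, 8577 without its replicates 1 and 3, 404 without pcDNA3.1 replicate 2, 236 without its replicates 1 and 3, 159 without pcDNA3.1-MEG3 replicate 2, 176 without its replicates 1 and 3, 3589 without siRNA replicate 2 and 1260 without its replicates 1 and 3.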

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

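Chosen only after the result was seen were the fit of 8 samples itself and the fit with negative control replicates 1 and 3 apart. So were those without replicates 1 and 3 together or without the second scans, the corrected normexp fit and the turned sign of the plasmid comparison. The same holds for the contrasts of siRNA with both plasmid groups and of pcDNA3.1-MEG3 with the negative control. The fit with 12 arrays as 12 samples is the design as planned, and the other alternatives were planned. Counts of calls are given in the order overexpression, knockdown, controls and difference, and the cause was not tested except where stated. The planned normexp correction gave 0, 0, 0 and 0 genes and 0 shared, because the model failed on 3 arrays: its background mean was -904, -796 and -1006 on pcDNA3.1 replicates 1 and 3 and siRNA replicate 2, against 7.31 to 13.9 on the others, where 7, 9 and 13 spots lay below local background. The median of all genes was -0.55, 0.75, 0.67 and -1.27 there. With the median background for such spots, 11, 2210, 3056 and 1550 genes were called, 3 shared, and Meg3 was -2.24 and passed (adjusted p = 0.0262). Quantile normalisation called 9 genes for overexpression and 7 shared. Median centring and the authors' values each gave 1 shared gene. Without a filter the knockdown gave 1964, the difference 1106 and the overlap 1, whereas probes well above background on all 12 arrays gave 22 for overexpression and 18 shared. A variance trend gave 8 for overexpression. Array weights gave 4807, 441 and 1005 in the first 3 comparisons, and Meg3, at -4.74, passed (adjusted p = 0.00315). The weights, lower where samples varied more, were 3.33 for pcDNA3.1-MEG3, 2.14 for pcDNA3.1, 0.607 for siRNA and 0.231 for the negative control. Relative to the spread of the samples compared, the single spread of the main fit was thus wide for the plasmids and narrow for the knockdown. The spread of the plasmid samples may be technical. Fitting only the arrays of the compared groups gave 1960 and 156, and Meg3, at -4.74, passed (adjusted p = 0.0292). A fold of at least 2 left 1865 and 2722 genes for the knockdown and controls, by construction. An unmoderated test per gene called 610, 0 and 2. With slide scan as a fixed block on the plasmid arrays alone, 11152 genes were called for overexpression, with Meg3 at -4.92 (adjusted p = 0.00263). For the other comparisons, slide scan as a random block on 12 arrays gave 14318, 16568 and 10415. Each scan of the negative control or siRNA arrays held 1 group, so this block cannot separate scan from group there. Counting 12 arrays as 12 samples gave 2997, 9839, 12072 and 8874, 1640 shared and Meg3 at -4.92 (adjusted p = 8.54e-05). Negative control replicates 1 and 3 as 2 samples gave 24 for overexpression, 4873 for the knockdown, 3192 for the difference, 18 shared and Meg3 at -4.74 (adjusted p = 0.0293). Set against both plasmid groups, siRNA gave 4590 genes, and pcDNA3.1-MEG3 against the negative control gave 3443. With an estimated correlation camera passed 0, 1 and 0 lists, and fry 0, 19 and 20. With the sign of the plasmid comparison turned the difference gave 604 genes. Over the alternatives, the adjusted p of Meg3 in the overexpression comparison ranged from 8.54e-05 to 0.66 and its direction did not change.

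With the replicate block 1, 1830 and 987 genes were called for overexpression, the knockdown and the difference, with 0 shared, while 3092 were called for the controls and 3, 6 and 5 lists passed. The numbers did not pair the samples. Leaving out samples, where a lone sample is assumed to vary like the other groups, gave 0 to 2 genes for overexpression (0 without pcDNA3.1 replicate 2, pcDNA3.1-MEG3 replicate 2, or replicates 1 and 3 of either group), 1948 to 7440 for the knockdown, 524 to 9155 for the controls and 159 to 8577 for the difference. With single arrays left out the knockdown ranged from 2910 to 7357, the latter without negative control replicate 2, with 4795 without siRNA replicate 2. Leaving out replicates 1 and 3 gave the knockdown 7440 (negative control) and 1948 (siRNA). The controls gave 1285 and 524 without pcDNA3.1 replicate 2 or replicates 1 and 3, and 7408 and 9155 without those of the negative control. The difference gave 5744 and 8577 for the negative control, 404 and 236 for pcDNA3.1, 159 and 176 for pcDNA3.1-MEG3, and 3589 and 1260 for siRNA. Meg3 ranged from -5.33 to -4.15, and 2 to 4, 4 to 7 and 5 to 8 lists passed (8 without negative control replicate 2).

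Directions that turned, none of them called in those alternatives apart from a list, were these. Under the planned normexp fit the overexpression values were -1.45 for Begain, -0.20 for Slc25a29, -0.32 for Wdr25, -0.68 for Tnni1 and -0.36 for Irf7, the knockdown values 1.53 for Dlk1, 1.94 for Meg3, 1.502 for Mirg, 1.08 for Wdr25, 0.25 for Rspo3 and 1.08 for Pdzrn4, and the control values 0.27 for Cnn1 and 0.34 for Lum. The control values of Begain and Mirg were -0.14 and -0.22 with quantile normalisation, -0.13 and -0.19 with median centring, and -0.14 and -0.22 with the authors' values. Median centring gave -0.16 for Slc25a29, -0.21 for Wars and -0.0595 for Wdr25. The mean of a gene's probes gave 0.18 for Meg3 in the knockdown. The corrected normexp fit gave -0.0898 for Begain in overexpression, and 0.24 for Dlk1 and 0.28 for Meg3 in the knockdown. Without replicates 1 and 3 of pcDNA3.1-MEG3 or of pcDNA3.1, Begain was -0.0266 and -0.0335, and without siRNA replicates 1 and 3 Dlk1 was 0.65. Without negative control replicate 2, Wdr25 was 0.0550 in the knockdown, and Mirg -0.11 and Wars -0.0468 in the controls. With single arrays left out, the highest value of Mirg in the controls was 0.47, without pcDNA3.1 replicate 2. The cell cycle inhibitors list passed fry between the controls in the direction opposite to camera, at a median of -0.0349. Signal over background limited Meg3, since 1 of the 6 negative control and siRNA arrays measured its brightest probe.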

Other observations

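The tests of explanations were chosen only after the results were seen. So were the contrasts of siRNA with both plasmid groups and of pcDNA3.1-MEG3 with the negative control. Set against the mean of both plasmid groups, the siRNA arrays had 35 of 50 contractile genes higher and 2 lower (median 2.27, camera adjusted p = 6.82e-21). Of 20 fusion genes 9 were higher and 0 lower (camera adjusted p = 0.000107), and of 54 extracellular matrix genes 23 were higher and 5 lower (camera adjusted p = 0.000966). Of 46 G1/S genes 9 were higher and 1 lower (camera adjusted p = 0.000966), and of 33 immediate early genes 10 and 2 (camera adjusted p = 0.0211). Interferon response genes went the other way, with 0 of 55 higher and 48 lower (median -2.26, camera adjusted p = 5.73e-28). On the arrays labelled pcDNA3.1-MEG3, 50 of 55 interferon response genes were higher than in the negative control and 0 lower (median 2.56, camera adjusted p = 7.98e-32). The same arrays also had 11 contractile genes higher and 1 lower (median 0.62, camera adjusted p = 0.000816), 11 of 46 G1/S genes higher and 1 lower (camera adjusted p = 0.0318), and 3 extracellular matrix genes higher and 18 lower (median -0.43, camera adjusted p = 3.24e-06). These camera values hold at a preset correlation: with an estimated correlation none of these lists passed, with an adjusted p of 0.0676 to 0.197 for siRNA against both plasmid groups and of 0.101 to 0.544 for pcDNA3.1-MEG3 against the negative control.

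Meg3 was brighter on the arrays labelled pcDNA3.1 than on those labelled pcDNA3.1-MEG3. A single cross-hybridising probe is argued against by the second probe, at -3.63 (SE 0.67). An exchange of the plasmid labels may explain it but stays open and untested: that the brightest probe was well above background on 0 of 3 arrays labelled pcDNA3.1-MEG3 is the observation itself and cannot also bear on its cause. A plasmid without effect in 1 group and Meg3 RNA from elsewhere in the other could give the same values, and no level near background tells them apart. No biological explanation was tested.

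Contractile genes were brighter on the siRNA arrays than on the negative control. The negative control slide as the whole cause is argued against, since the median against both plasmid groups was 2.27 (2.03 to 2.52 over 8 pairings of samples) beside 2.56. The siRNA slide stays open because it held 0 arrays of another group. Less Meg3 RNA also stays open, since no fold can be given: the fitted change of -0.62 (SE 0.47) in Meg3 rested on signals well above background on 1 negative control array and 0 siRNA arrays.

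The negative control arrays alone were scanned in a different calendar month from the others. They could stand apart from all other groups, which would raise or lower genes in the knockdown comparison. The test asks whether the called genes also differed between the siRNA arrays and both plasmid groups. It was redefined several times after its earlier outcomes had been seen, so the forms are given side by side and none was preferred. With no array held out of the calling, the 1900 genes called higher had a median of 0.60 beside 1.04 against the negative control, and the 1137 called lower -0.44 beside -1.33. With 1 siRNA sample held out and measured, the genes called higher had 0.95 beside 1.54 or -0.24 beside 0.76, and those called lower -0.25 beside -0.91 or -0.30 beside -0.27. With 1 sample each of siRNA and the negative control held out, the medians over 4 splits were 0.0672 to 0.30 for higher (0.24 to 0.53 against the negative control) and -0.37 to -0.18 for lower (-0.34 to -0.0920). Relative to the median of all genes, the same splits gave 0.15 to 0.35 (0.21 to 0.40) and -0.33 to -0.14 (-0.35 to -0.25). The forms gave different answers: the ratio of both medians ran from -0.315 to 1.01 for higher and from 0.273 to 2.55 for lower. The explanation is therefore left open in both directions. The transfected nucleic acids, which differed between the plasmid and siRNA groups, remain an open and untested difference.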
